A study of Rattus norvegicus with 6 samples.

How the data were processed

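Total RNA came from fresh aortic rings of male rats aged 1 to 2 months (day 0) and from ring cultures in collagen gel after 1 day in serum-free medium (day 1), 3 arrays per group. Per the labels, rings or cultures were pooled by 4 to 6 before extraction, and 200 ng of total RNA was biotin-labelled with the Affymetrix whole-transcript sense protocol. The deposited table holds log2 expression values, 1 per transcript cluster and array, for 27342 rows and 6 arrays. The log2 scale was inferred from the range of the values, which reach 14.16. The submitters' processing notes name limma; background correction, normalization and summarisation are not given in the sources used here. Array medians lay between 5.87 and 5.95, so the values were used without further scaling. The spread of values was wider on day 1. Upper quartiles were 7.83 to 7.87 on day 0 and 7.93 to 7.95 on day 1. Lower quartiles were 4.32 to 4.39 on day 0 and 4.27 to 4.29 on day 1. A normalization that equalises arrays sets changes relative to the bulk of genes, and log2 values of dim rows understate fold changes.

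Rows were named through the array annotation given with the series, with symbols updated by gene ID or accession against a rat gene table of assembly GRCr8, used for names only. A total of 15097 rows had exactly 1 symbol, 323 had several and 11922 had none. Symbols were matched by Entrez gene ID in 15067 rows and by transcript accession in 6, and kept as annotated in 24. Rows with several symbols or none were left out of the main comparison and used only with every row as a feature. Of several rows of a gene, which 499 genes had, the row with the highest mean over the 6 arrays was kept, giving 14324 genes. No coordinates are printed, since the array's genome build is not given in the sources used here.

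Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, no filter on dim genes, no block), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Labels call the arrays biological replicates but do not say whether pools shared animals, so p-values measure the spread between these pools. A set of 43 gene lists, with 893 of 1038 memberships measured, was tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists; camera with an estimated correlation and fry were alternatives. Fry asks whether members move one way on balance and does not compare a list with other genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

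The lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, leaving out genes without an informative name. It adds up to 4 members of each list with the largest absolute change past the threshold and the largest change against the majority, or the 2 largest where none passes. It also names, where measured, Tnf, Il1b, Il6, Ccl2, Orm1, Vegfa, Angpt1, Angpt2, Kdr, Fgf2, Pdgfb, Dll4, Mmp9, Acta2, Cd68 and Adipoq, of which 14 of 16 were measured. The text may name fewer list members where a count summarises the list.

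The fit was tested on simulated data with 200 changed genes among 14324, with the means and spreads of the real arrays. It recovered 70.1% of genes changed by 0.5 log2 units, 94.0% of those changed by 1 and 98.5% of those changed by 2, and 7 of its 182 calls were unchanged genes. In the real data a far larger share, 48.3% of genes, passed the threshold. The adjustment depends on that share, so these rates need not hold for the real fit. In a second simulation the shifted list was called and 0 others were. Genes were drawn independently there, so it cannot show how camera behaves with correlated members. Alternatives were quantile normalization, median centring, 2 filters on dim genes (the dimmest 25%, or those under the median, by mean over the arrays), the mean or the most variable row of a gene, every row as a feature, an intensity trend with robust prior, array weights, an unmoderated unequal-variance test, treat against 1.5-fold, the replicate number as a block, and each array left out in turn.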

Results

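Gene expression was measured in the aorta of young male rats, in rings freshly cut from the vessel (day 0) and in rings embedded in collagen gel and kept for 1 day in serum-free medium (day 1). Each group held 3 biological replicates. A replicate was pooled RNA from 4 to 6 rings or cultures, hybridised to its own whole-transcript array. The aortic ring assay is a culture model of angiogenesis, in which new vessels later sprout from the cut vessel wall. The comparison asks which transcripts differ after the first day. The 6 arrays had median log2 values between 5.87 and 5.95, and 14324 genes were tested. The number of arrays limits the precision. Values after ± are standard errors of the log2 change (day 1 minus day 0, n = 3 per group) unless given as SD.

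After 1 day of culture, transcripts of contractile smooth muscle were lower. Many transcripts of acute phase proteins, chemokines, oxidative stress enzymes and DNA replication factors were higher. Serpina3n, a serine protease inhibitor of the acute phase, had the largest rise of any gene named here, from 6.61 ± 0.07 (SD, n = 3) to 12.48 ± 0.02 (SD, n = 3), a 58.4-fold change. Cnn1, the smooth muscle actin-binding protein calponin, had the largest fall, from 12.59 ± 0.03 (SD, n = 3) to 6.86 ± 0.10 (SD, n = 3). Other large rises were those of Chi3l1 (5.38 ± 0.11), the cystine transporter gene Slc7a11 (5.29 ± 0.09) and the B cell chemokine gene Cxcl13 (5.13 ± 0.11). Others were those of the urea transporter gene Slc14a1 (4.91 ± 0.10), the cytochrome P450 gene Cyp1b1 (4.84 ± 0.13) and the heme oxygenase gene Hmox1 (4.65 ± 0.11). Among the largest falls were the calsequestrin gene Casq2 (-5.15 ± 0.12), the G protein regulator Rgs4 (-4.66 ± 0.11), Cytl1 (-4.64 ± 0.12) and the phospholamban gene Pln (-4.20 ± 0.08). By limma with Benjamini-Hochberg adjustment, 6915 of the 14324 genes (48.3%) passed an adjusted p of 0.05, of which 3947 rose and 2968 fell. A change of at least 2-fold was reached by 592 of the genes that rose and 589 of those that fell, and one of at least 8-fold by 33 and 28. The arrays of both groups did not overlap in 8152 genes, where chance gives 10%. Pearson correlations across genes were 0.996 to 0.997 within a group and 0.959 to 0.963 between groups, and the first principal component, which parted the groups, held 89.6% of the variance.

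**Figure D1:**
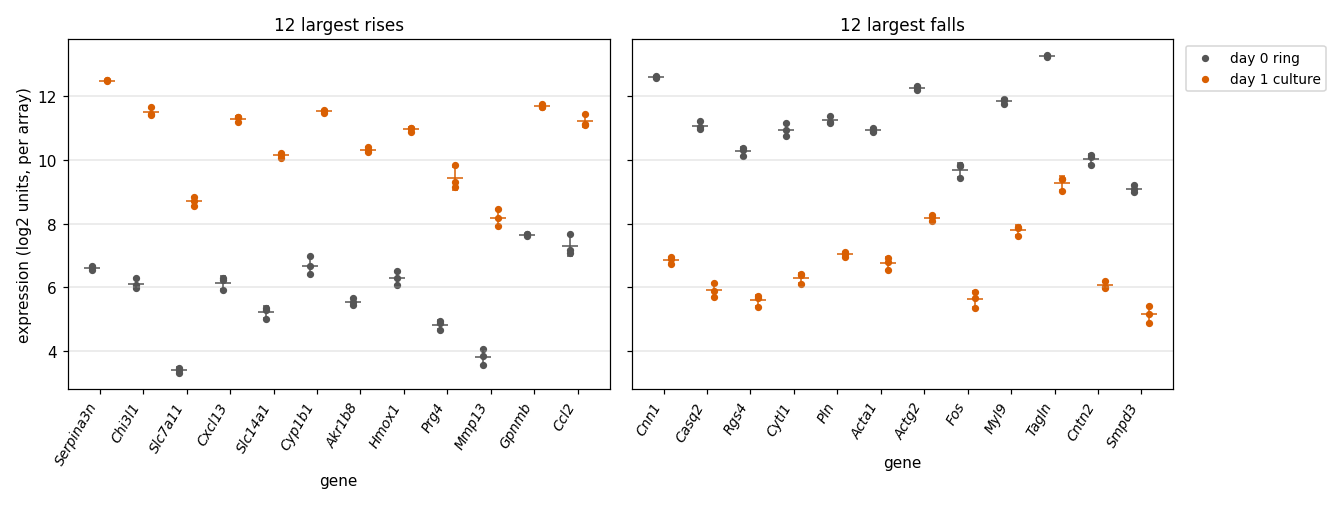
Expression per array, in log2 units, of the 12 genes with the largest rise (left) and the 12 with the largest fall (right); points are the 3 arrays of a group, dashes their mean and bars the SD. The rule that chose the 24 genes requires groups that do not overlap. Log2 changes run from Serpina3n (5.87) to Ccl2 (3.90) among the rises and from Cnn1 (-5.73) to Smpd3 (-3.93) among the falls.

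Gene groups were followed through 43 lists written before the data were examined. Counts of members adjusted over the list alone equalled those adjusted over all genes unless given. With camera at a preset correlation, 25 lists passed an adjusted p of 0.05, 14 upward and 11 downward. None of the 25 calls held with an estimated correlation, where the lowest adjusted p was 0.167. For the Wnt, heat shock, dendritic cell and brown adipocyte lists the estimate lay under the preset 0.01. Their lost calls therefore do not show a correlation above the preset. Other splits of the same 6 arrays, which called 0 genes, also called 13 to 17 lists. Those splits mix the groups, so part of the day difference stays in the contrast and the rest widens the spread. Their counts are therefore not a chance level.

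All 20 measured members of the contractile smooth muscle list fell, 18 of them at least 2-fold, with a median log2 change of -2.76 (camera adjusted p = 4.68e-17; adjusted p = 0.167 with an estimated correlation). Besides Cnn1, Casq2 and Pln, they included the enteric actin gene Actg2 (-4.08 ± 0.07), the myosin light chain gene Myl9 (-4.05 ± 0.09) and the transgelin gene Tagln (-3.98 ± 0.11). Of 11 pericyte markers 3 rose and 5 fell, with Rgs5 at -3.78 ± 0.06 and Notch3 at -1.70 ± 0.07 (adjusted p = 0.102). The pericyte list passed with quantile normalization (adjusted p = 0.0416) and without day 0 replicate 2 (adjusted p = 0.0357). Skeletal and cardiac muscle markers fell in 10 of 23 cases, 12 adjusted over the list alone, and rose in 2 (median -0.17, adjusted p = 0.00271; adjusted p = 0.184 with an estimated correlation). Acta1, an actin of skeletal muscle, was at -4.16 ± 0.10 and the creatine kinase gene Ckm at -2.04 ± 0.10. Heat shock and chaperone genes fell in 11 of 17 cases and rose in 5 (median -0.28, adjusted p = 0.0215; adjusted p = 0.184 with an estimated correlation). Dnajb4 was at -2.39 ± 0.06, the small chaperone gene Cryab at -2.26 ± 0.07 and Hspb8 at 1.53 ± 0.08.

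Inflammatory mediators rose in several groups. Of 24 chemokine genes 17 rose and 2 fell (median 1.04, adjusted p = 1.59e-04; adjusted p = 0.242 with an estimated correlation). After Cxcl13, the largest changes were those of the monocyte attractant gene Ccl2 (3.90 ± 0.16), the fractalkine gene Cx3cl1 (3.87 ± 0.08) and Ccl7 (2.77 ± 0.19). Among 14 acute phase genes 9 rose and 0 fell (median 0.74, adjusted p = 0.00271; adjusted p = 0.273 with an estimated correlation). Among them were the lipopolysaccharide-binding protein gene Lbp (3.01 ± 0.06) and the orosomucoid gene Orm1 (2.40 ± 0.12). Members of the Toll-like receptor pathway rose in 11 of 14 cases and fell in 2 (median 0.79, adjusted p = 1.89e-04; adjusted p = 0.224 with an estimated correlation). The interleukin-1 receptor gene Il1r1 was at 2.74 ± 0.07, Ly96 at 2.31 ± 0.08, Myd88 at 1.77 ± 0.07 and Tlr3 at -0.61 ± 0.10. NF-kappaB feedback genes and targets rose in 16 of 22 cases (median 0.63, adjusted p = 1.78e-04; adjusted p = 0.331 with an estimated correlation). Sod2 (2.01 ± 0.06) and the adhesion molecule gene Icam1 (1.59 ± 0.08) rose, and the cyclooxygenase gene Ptgs2 fell by 2.30 ± 0.11. Ptx3 of the same list rose by 3.31 ± 0.44, and by 2.70 without day 1 replicate 3, in which it stood at 9.54 against 7.71 in each of the other day 1 arrays.

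Cytokine genes went both ways. Of 21 measured, 9 rose, 10 adjusted over the list alone, and 4 fell (median 0.39, adjusted p = 0.217). Il6 rose by 2.96 ± 0.42 with a day 1 SD of 0.98, the interleukin-1 antagonist gene Il1rn by 1.40 ± 0.21 and Il11 by 1.37 ± 0.13, and the alarmin gene Il33 fell by 1.36 ± 0.11. Tnf rose by 0.63 ± 0.16 (adjusted p = 0.0133). Il1b was higher by 0.72 ± 0.28 but missed the threshold (adjusted p = 0.0641). It passed without day 1 replicate 2 (adjusted p = 0.0272) or without day 1 replicate 3 (0.35, adjusted p = 0.00962). It also passed with quantile normalization (adjusted p = 0.0459), median centring (adjusted p = 0.0415) or without the dimmest 25% of genes (adjusted p = 0.0391).

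Interferon-stimulated genes rose in 22 of 23 cases with 16 of them at least 2-fold (median 1.29, adjusted p = 4.53e-09; adjusted p = 0.242 with an estimated correlation). The antiviral genes Rsad2 (3.66 ± 0.19), Ifit3 (3.25 ± 0.22), Mx1 (2.40 ± 0.12) and Mx2 (2.24 ± 0.12) had the largest changes of the list.

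Genes of oxidative and metabolic stress rose as well. Of 19 NRF2 targets and metallothioneins 17 rose (median 1.18, adjusted p = 5.03e-09; adjusted p = 0.167 with an estimated correlation). The aldo-keto reductase gene Akr1b8 was at 4.76 ± 0.08 and the metallothionein gene Mt2A at 3.89 ± 0.07 (4.67 on the more variable of its 2 rows), while Gsta4 fell by 0.95 ± 0.07. Hypoxia and glycolysis genes rose in 22 of 29 cases (median 0.80, adjusted p = 2.41e-08; adjusted p = 0.167 with an estimated correlation). Among them were the carbonic anhydrase gene Car9 (3.04 ± 0.16), the glucose transporter gene Slc2a1 (1.83 ± 0.06) and the pyruvate kinase gene Pkm (1.64 ± 0.07). Unfolded protein and amino acid response genes rose in 21 of 25 cases (median 0.48, adjusted p = 2.24e-07; adjusted p = 0.167 with an estimated correlation), with the asparagine synthetase gene Asns at 2.31 ± 0.09 and Trib3 at 2.08 ± 0.17. Among 21 p53 targets and apoptosis genes 14 rose, 16 adjusted over the list alone, and 3 fell (median 0.38, adjusted p = 0.00684; adjusted p = 0.247 with an estimated correlation). Gadd45a was at 3.75 ± 0.10, Bid at 1.90 ± 0.10 and the death receptor gene Fas at -0.88 ± 0.10. That list missed the threshold without genes under the median mean (adjusted p = 0.398). Oxidative phosphorylation and tricarboxylic acid cycle genes rose in 4 and fell in 9 of 30 cases (median -0.03, adjusted p = 0.244), with Ogdh at -0.87 ± 0.05; with quantile normalization the list passed, downward (adjusted p = 0.0108).

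Replication genes rose. In the G1 to S list 27 of 30 members rose, 28 adjusted over the list alone, and 17 of them at least 2-fold (median 1.18, adjusted p = 4.67e-10; adjusted p = 0.167 with an estimated correlation). The replication licensing genes Cdc6 (2.16 ± 0.10), Mcm6 (2.01 ± 0.07) and Mcm7 (1.93 ± 0.09) and the cyclin gene Ccne1 (1.94 ± 0.21) led it, and Ccnd2 fell by 0.69 ± 0.07. In the G2 and mitosis list 20 of 27 members rose, 1 of them at least 2-fold (median 0.39, adjusted p = 1.89e-04; adjusted p = 0.167 with an estimated correlation), namely the spindle checkpoint kinase gene Ttk (1.12 ± 0.14). This list missed the threshold without genes under the median mean (adjusted p = 0.0933). Ribosome biogenesis genes and MYC targets rose in 21 of 23 cases (median 0.78, adjusted p = 2.41e-08; adjusted p = 0.167 with an estimated correlation), with Gar1 at 1.22 ± 0.09, Wdr12 at 1.16 ± 0.07 and the spermidine synthase gene Srm at -0.27 ± 0.06.

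Immediate early genes fell in 17 of 25 cases and rose in 4 (median -0.59, adjusted p = 1.62e-04; adjusted p = 0.224 with an estimated correlation). Fos was at -4.05 ± 0.15, the phosphatase gene Dusp1 at -3.84 ± 0.08, Ccn1 at -3.48 ± 0.10 and the nuclear receptor gene Nr4a1 at -2.87 ± 0.14. Myc rose by 2.41 ± 0.17. Glucocorticoid-responsive genes rose in 6 and fell in 6 of 17 cases (adjusted p = 0.980), with Fkbp5 at 2.16 ± 0.08. Dusp1 (-3.84) also stands in this list. Circadian clock genes rose in 6 and fell in 7 of 14 cases, 8 adjusted over the list alone (adjusted p = 0.501), with Bhlhe40 at 2.37 ± 0.06 and Per2 at -1.06 ± 0.06.

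Angiogenic growth factors and receptors rose in 20 and fell in 9 of 33 cases (median 0.33, adjusted p = 0.0527). The list passed without day 0 replicate 1 (adjusted p = 0.0451) or without day 0 replicate 2 (adjusted p = 0.0444). The placental growth factor gene Pgf rose by 2.01 ± 0.08, the hepatocyte growth factor gene Hgf by 1.79 ± 0.09 and its receptor gene Met by 1.86 ± 0.12. Pdgfra rose by 1.85 ± 0.07, Vegfa by 0.64 ± 0.09, Pdgfb by 0.58 ± 0.07 and Angpt2 by 0.45 ± 0.07. Igf1 was at -1.64 ± 0.10 and Angpt1 at -0.51 ± 0.11, both past the threshold, and Fgf2 was at -0.07 ± 0.07 (adjusted p = 0.457). Kdr and Acta2 were not analysed here. Tip cell and Notch pathway genes rose in 7 and fell in 8 of 21 cases (adjusted p = 0.491), with the tip cell genes Esm1 at 3.13 ± 0.12 and Dll4 at 1.15 ± 0.08, Heyl at -1.51 ± 0.07 and Efnb2 at -1.44 ± 0.07.

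Fibrillar and basement membrane genes fell in 18 of 27 cases, 19 adjusted over the list alone, and rose in 7 (median -0.59, adjusted p = 1.29e-04; adjusted p = 0.273 with an estimated correlation). The elastin gene Eln was at -2.60 ± 0.07, Col14a1 at -2.11 ± 0.07, Col5a1 at -1.91 ± 0.06 and Lum at 0.88 ± 0.07. Metalloproteinase and plasminogen system genes rose in 14 of 27 cases, 15 adjusted over the list alone, and fell in 9 (adjusted p = 0.283). The collagenase gene Mmp13 rose by 4.36 ± 0.16, the urokinase gene Plau by 2.92 ± 0.09, the stromelysin gene Mmp3 by 2.89 ± 0.12 and the inhibitor gene Timp1 by 2.40 ± 0.07, and Adamts9 fell by 2.38 ± 0.11. Mmp9 rose by 0.43 ± 0.14 (adjusted p = 0.0389). It missed the threshold without day 0 replicate 1 (adjusted p = 0.0906), replicate 2 (adjusted p = 0.0981) or replicate 3 (adjusted p = 0.0626). Without day 1 replicate 3 its change was 0.25 (adjusted p = 0.0303). Provisional matrix genes rose in 7 and fell in 7 of 15 cases (adjusted p = 0.801), with Lgals3 at 2.58 ± 0.07, the hyaluronan receptor gene Cd44 at 2.54 ± 0.06 and Lox at -1.31 ± 0.07. Integrin and adhesion genes rose in 6 and fell in 4 of 16 cases (adjusted p = 0.772), with Itga11 at -2.94 ± 0.09, Mcam at -2.54 ± 0.07 and Itga2 at 1.90 ± 0.06. Wnt pathway genes fell in 16 of 26 cases and rose in 1, 2 adjusted over the list alone (median -0.39, adjusted p = 1.78e-04; adjusted p = 0.167 with an estimated correlation). The secreted inhibitor genes Sfrp2 and Sfrp1 were at -2.64 ± 0.10 and -2.33 ± 0.06. TGF-beta and BMP pathway genes rose in 8 and fell in 10 of 23 cases (adjusted p = 0.711), with Tgif1 at 2.91 ± 0.09, Tgfb1 at 1.64 ± 0.07 and Bmp6 at -2.16 ± 0.07. Median, mean and camera direction differed in sign for the provisional matrix, integrin, TGF-beta, glucocorticoid and mesothelial lists.

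**Figure D2:**
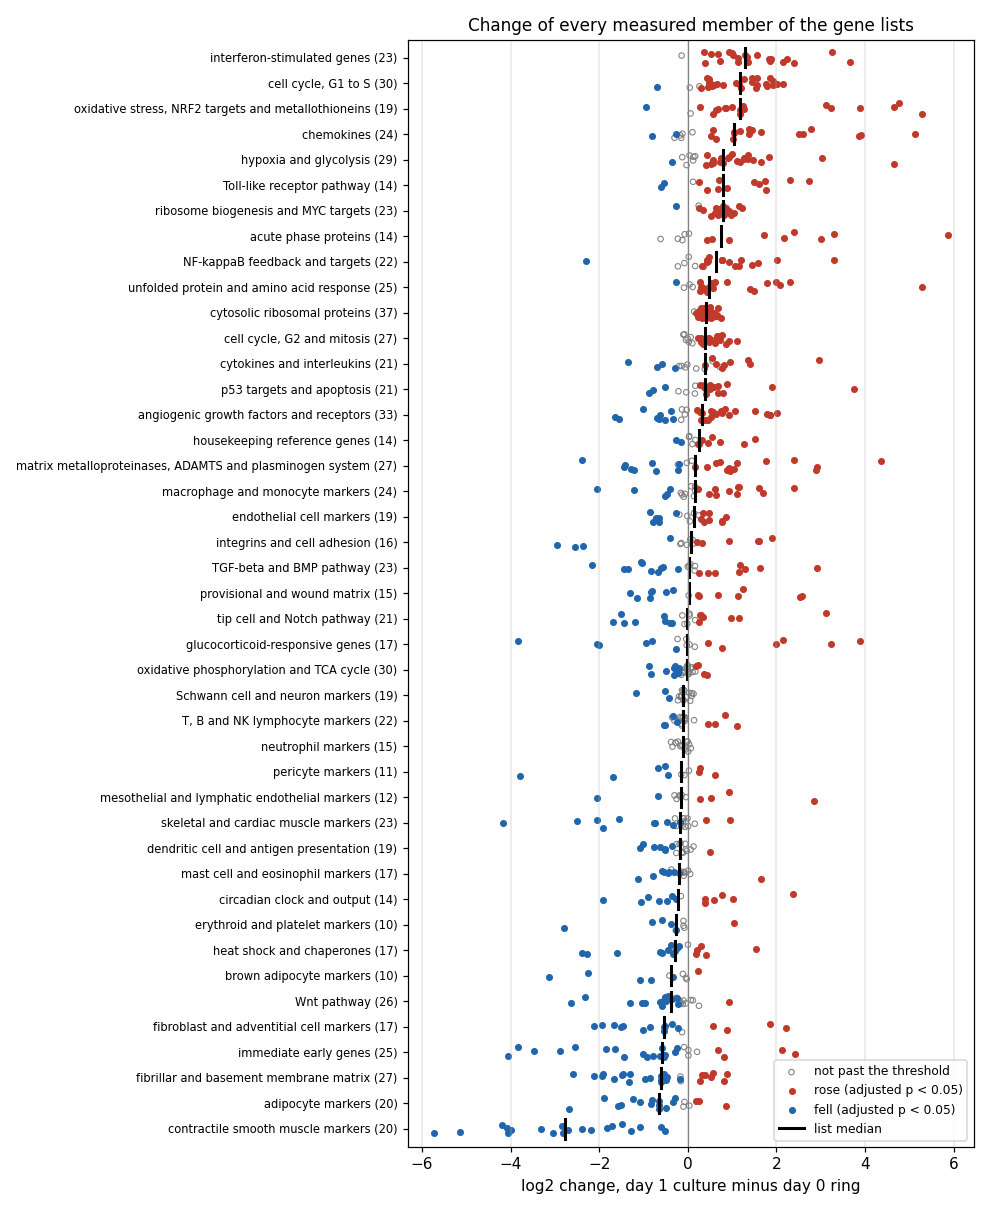
Log2 change (day 1 minus day 0) of each measured member of the 43 gene lists, with the number of members in brackets; filled points passed an adjusted p of 0.05 (red rose, blue fell), open points did not, and black bars are list medians. The contractile smooth muscle list lies lowest (median -2.76) and the interferon-stimulated list highest (median 1.29).

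Endothelial markers rose in 8 of 19 cases, 9 adjusted over the list alone, and fell in 6 (median 0.14, adjusted p = 0.801), with Egfl7 at 0.87 ± 0.10 and Edn1 at -0.86 ± 0.11. Macrophage and monocyte markers rose in 11 and fell in 5 of 24 cases (median 0.16, adjusted p = 0.147), with Fcgr2b at 2.40 ± 0.16, Cd68 at 1.70 ± 0.06, Cd14 at 1.61 ± 0.07 and Lyve1 at -2.05 ± 0.08. Fibroblast and adventitial markers fell in 12 of 17 cases and rose in 4 (median -0.53, adjusted p = 0.00486; adjusted p = 0.340 with an estimated correlation). Pi16 was at -1.94 ± 0.09 and Gfpt2 at 2.21 ± 0.11. Adipocyte markers fell in 14 of 20 cases and rose in 3 (median -0.65, adjusted p = 3.76e-04; adjusted p = 0.242 with an estimated correlation). The aquaporin gene Aqp7 was at -2.69 ± 0.17 and the adiponectin gene Adipoq at -1.08 ± 0.11. Brown adipocyte markers fell in 5 of 10 cases, 6 adjusted over the list alone, and rose in 1 (median -0.38, adjusted p = 0.0159; adjusted p = 0.184 with an estimated correlation). The uncoupling protein gene Ucp1 was at -3.13 ± 0.21. Antigen presentation and dendritic cell genes fell in 7 of 19 cases and rose in 1 (median -0.19, adjusted p = 0.0153; adjusted p = 0.184 with an estimated correlation). The invariant chain gene Cd74 was at -1.08 ± 0.12.

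Mast cell and eosinophil markers fell in 8 of 17 cases and rose in 1, the receptor gene Kit at 1.65 ± 0.07 (median -0.20, adjusted p = 0.0293; adjusted p = 0.242 with an estimated correlation). That list missed the threshold with quantile normalization (adjusted p = 0.101), without the dimmest 25% of genes (adjusted p = 0.335) and without day 0 replicate 3 (adjusted p = 0.0640). Lymphocyte markers rose in 4 and fell in 4 of 22 cases (median -0.11, adjusted p = 0.283), with Blk at 1.11 ± 0.20, Il7r at 0.84 ± 0.11 and Cd2 at -0.55 ± 0.06. Schwann cell and neuron markers fell in 3 of 19 cases, 2 adjusted over the list alone, and rose in 0 (adjusted p = 0.0968), with Ncam1 at -1.17 ± 0.08. Erythroid and platelet markers fell in 5 of 10 cases and rose in 1 (adjusted p = 0.0610). That list passed without day 0 replicate 3 (adjusted p = 0.0245) and with camera on ranks (adjusted p = 0.0440). The hemoglobin gene Hbb was at -2.79 ± 0.15 and Pf4 at 1.05 ± 0.07. Mesothelial and lymphatic markers rose in 4 and fell in 2 of 12 cases (adjusted p = 0.733), with Pdpn at 2.84 ± 0.06. By limma, 0 of 15 neutrophil markers passed the threshold (list adjusted p = 0.217; 0 adjusted over the list alone). Fpr1 was at -0.38 ± 0.14 (adjusted p = 0.0556), and at -0.53 (adjusted p = 0.00730) without day 1 replicate 3. It missed the threshold with any other array left out, and was at -0.23 (adjusted p = 0.132) without day 1 replicate 1. Retnlg was at -0.35 ± 0.18 (adjusted p = 0.155), and passed without day 0 replicate 3 (adjusted p = 0.0355) or without day 1 replicate 1 (adjusted p = 0.0483). With any other array left out Retnlg missed the threshold, and was at -0.22 (adjusted p = 0.382) without day 1 replicate 2.

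Of 14 housekeeping genes 8 rose and 2 fell (median 0.24, adjusted p = 0.0228; adjusted p = 0.273 with an estimated correlation), and 6 rose and 2 fell with quantile normalization (median 0.09, adjusted p = 0.275). The housekeeping list also missed the threshold without the dimmest 25% of genes (adjusted p = 0.0878) and without genes under the median mean (adjusted p = 0.215). The transferrin receptor gene Tfrc was at 1.53 ± 0.09, Pgk1 at 1.27 ± 0.10, Gapdh at 0.72 ± 0.06 and Actb at -0.27 ± 0.06. Of the 14 genes 4 also stand in another list, and Pgk1 and Gapdh stand in the hypoxia and glycolysis list. Cytosolic ribosomal protein genes rose in 36 of 37 cases, 37 adjusted over the list alone (median 0.41, adjusted p = 4.53e-09; adjusted p = 0.184 with an estimated correlation), and in 21 of 37 with quantile normalization (median 0.22). The median change of all genes was -0.01.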

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

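Of the tests here, the splits of the arrays, the comparison of cell type lists, the day 0 percentile of immediate early genes and the comparisons of cell cycle lists were chosen after the results were seen. Rows of the array without a gene symbol, which the main comparison did not use, held signal that differed between the groups: 208 of them rose at least 2-fold on day 1 and 276 fell, with 3381 of 11922 (28.4%) past the threshold, against 44.9% of rows with 1 symbol. Rows with several symbols rose at least 2-fold in 3 cases and fell in 6.

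Of the 10 splits of the 6 arrays into groups of 3, only the real split, 1 of 10, gave as many as 6915 genes, 1181 genes of at least 2-fold and 25 lists; the highest of the other splits gave 0 genes, 0 genes of at least 2-fold and 17 lists. With 10 splits a share under 0.05 cannot be reached. Because the other splits mix day 0 and day 1 arrays, the day difference widens their spread and partly stays in their contrast. Their counts are therefore not a chance level.

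The contractile smooth muscle list fell by a median of 2.76. A general fall of bright genes is argued against, since the lowest median among 10000 random lists matched on day 0 level was -0.88. A lower share of smooth muscle cells, with nothing else changed, would raise the markers of every other cell type alike. The macrophage list (mean change 0.31 ± 0.06, SE over arrays) and the fibroblast list (-0.43 ± 0.04) instead moved apart by 0.74 ± 0.03. The endothelial list was at 0.04 ± 0.05. Of the macrophage, fibroblast and endothelial markers 2 of 24, 7 of 17 and 4 of 19 also stand in another list. The gap cannot decide the question, since expression changes within the other cell types would part these lists too. Fibroblast markers went both ways, with Pdgfra at 1.85 and Col14a1 at -2.11. Loss with nothing else changed would also lower markers found only in smooth muscle cells by a common factor. The quartiles of the contractile list were -4.00 and -1.66. These unequal falls argue against loss as the whole cause, for members that other cells do not express. Which members those are was not tested. A loss of smooth muscle cells and lower expression within them both stay open as parts of the fall, and no test here separates them.

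Immediate early genes fell by a median of 0.59. The lowest median among 10000 matched random lists was -0.38, which argues against a general fall of bright genes. Their median percentile among all genes was 84.9 on day 0 and 67.8 on day 1. Induction by the harvest itself may have raised the day 0 level, and cannot be told apart from other causes because no tissue left unhandled was measured.

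G1 to S genes rose by a mean of 1.08 ± 0.03 (SE over arrays) and mitotic genes by 0.41 ± 0.03, a difference of 0.67 ± 0.02 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Compression through a lower day 0 level of the mitotic genes is argued against, since the day 0 medians were 6.59 (G1 to S) and 6.62 (mitotic). Among the 19 and 23 members with a day 0 level between 5.5 and 8 the difference in change was 0.75 ± 0.03. That range still holds dim genes, so compression within it was not tested. Entry into S phase ahead of mitosis is a candidate explanation that was not tested, and later time points would be needed.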

How the results depend on the processing

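All settings here were planned before the data were examined. The count of genes ranged from 4977 (unmoderated unequal-variance test) to 10254 (every row as a feature, where more features are tested), against 6915, and from 6166 to 6506 with an array left out; 4900 of the 6915 calls were shared with the unequal-variance test and 5924 with quantile normalization, in the same direction. Genes changed at least 2-fold numbered 874 to 1708; treat, which tests against the smaller change of 1.5-fold, called 1550. Rises made up 50.1% of the genes changed at least 2-fold, 46.3% with quantile normalization, 54.8% with median centring and 48.4% with every row as a feature. Lists past the threshold numbered 20 to 27, except 0 with an estimated correlation and 38 with fry. The cause was not tested over the lists as a whole. For the Wnt (-0.005), heat shock (-0.026), dendritic cell (-0.012) and brown adipocyte (-0.001) lists the estimated correlation lay under the preset 0.01. A correlation above the preset therefore cannot account for the loss of those calls. The first principal component's share moved from 89.6% to 93.9% without the dimmest 25% of genes and 96.6% without genes under the median mean; the cause was not tested. No called list and no named gene past the threshold changed direction, among the 43 lists and genes named by rule or among the 8 lists and their members written after the results were seen, which were run through the same settings. Over named genes and settings 2652 comparisons kept their side of the threshold, 34 lost it and 8 gained it; over lists the numbers were 669, 33 and 21. Rising genes made up 57.1% of calls and from 53.4% (quantile normalization) to 65.6% (without genes under the median mean, where the median change of all genes was 0.13), with 63.7% with median centring and 61.2% with the unequal-variance test. The replicate block gave 6686 genes, 1181 of at least 2-fold and 26 lists, with the erythroid and platelet list past the threshold (camera adjusted p = 0.0468). Deviations of same-numbered arrays correlated by 0.011, 0.019 and 0.036, and those of other pairs by -0.054 to 0.036. With 3 arrays per group such values cannot show whether the numbers pair the arrays. The pseudocounts planned for a linear table were not run, since the values are log2. Signal over background was not given, so dim genes carry no detection limit.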

Other observations

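The 8 lists here, their tests, the genes named from them and the counts by array were chosen after the results were seen. Camera p-values of these lists were adjusted over the 8 lists alone, without the lists fixed earlier. That correction is milder, and the lists were chosen on the same data. Their adjusted p-values, including those with an estimated correlation, therefore cannot be set beside those of the lists fixed earlier. By limma, 29 of 29 proteasome genes rose (median 0.53, camera adjusted p = 1.11e-09; adjusted p = 0.0409 with an estimated correlation), with the regulatory subunit gene Psmd11 at 1.04. Lysosomal genes rose in 20 of 24 cases and fell in 1 (median 0.67, adjusted p = 9.98e-08; adjusted p = 0.0938 with an estimated correlation), with the cholesterol transporter gene Npc1 at 1.93, the protease gene Ctsb at 1.31 and Ctsh at -0.72. Cholesterol synthesis genes rose in 13 of 16 cases (median 0.71, adjusted p = 4.99e-06; adjusted p = 0.0938 with an estimated correlation), with Insig1 at 2.13 and Msmo1 at 2.00. Aryl hydrocarbon receptor targets rose in 5 of 8 cases (median 2.05, adjusted p = 0.00156; adjusted p = 0.0938 with an estimated correlation), with Cyp1b1 at 4.84, Xdh at 3.65, Nqo1 at 3.12 and the receptor gene Ahr at 3.09, while Cyp1a1 stood at -0.10 (adjusted p = 0.277), Ahrr at -0.08 (adjusted p = 0.561) and Cyp1a2 at -0.004 (adjusted p = 0.986). Ahr encodes the receptor itself, Nqo1 and Aldh3a1 also stand in the NRF2 list, and Cyp1b1 was known to be among the largest rises when the list was written. Complement genes rose in 6 and fell in 3 of 14 cases (adjusted p = 0.269), with Serping1 at 1.97 and Cfp at -1.34; 4 of the 14 also stand in a list fixed earlier, as does 1 of the 24 lysosomal genes.

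Members of the potassium and calcium channel list fell in 18 of 25 cases and rose in 2 (median -0.47, camera adjusted p = 4.72e-06). With an estimated correlation the adjusted p was 0.0938. Kcnmb1 was at -2.84 and the ryanodine receptor gene Ryr2 at -1.91. The falls include genes of the list that are not channels, the calcium pump genes Atp2b4 (-2.39) and Atp2a2 (-0.74) and the exchanger gene Slc8a1 (-0.47). Kcnmb1, Ryr2 and Kcnj8 also stand in lists fixed earlier. Regulators of G protein signalling and cGMP-calcium coupling fell in 14 of 19 cases and rose in 3 (median -0.88, adjusted p = 1.80e-05; adjusted p = 0.0938 with an estimated correlation), with Rgs5 at -3.78, the phosphatase inhibitor gene Ppp1r14a at -3.10 and the kinase gene Prkg1 at -1.07. Rgs5 also stands in the pericyte list, and Rgs4 was known to be among the largest falls when the list was written. Receptors for vasoactive ligands fell in 14 of 27 cases and rose in 5 (median -0.26, adjusted p = 0.00561; adjusted p = 0.298 with an estimated correlation). The purinergic receptor gene P2rx1 was at -3.23, the angiotensin receptor gene Agtr2 at -2.98 and the serotonin receptor gene Htr2b at 2.99.

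Day 1 replicate 3 stood at least 0.5 above both other day 1 arrays in 13 of the 115 members of the cytokine, chemokine, NF-kappaB, acute phase, Toll-like receptor and macrophage lists; the other day 1 arrays did so in 1 and 0. Among all 14324 genes the numbers were 31, 40 and 25 for replicates 3, 1 and 2. Of the genes named by rule 7 stood that far above, namely Ptx3 (9.54 against 7.71 and 7.71), Il6 (7.38 against 5.71 and 5.65), Il1b (6.72 against 5.66 and 5.52), Ccl7 (9.75 against 9.01 and 9.01), Fcgr2b (8.01 against 7.46 and 7.38), Prg4 (9.82 against 9.15 and 9.29) and Mmp9 (5.47 against 4.89 and 4.96). Without that array the mean change of the chemokine list was 1.19 in place of 1.29, of the acute phase list 1.27 in place of 1.38, of the NF-kappaB list 0.60 in place of 0.69 and of the cytokine list 0.32 in place of 0.40. Day 0 replicates 1, 2 and 3 stood at least 0.5 below both other day 0 arrays in 44, 34 and 42 of all genes, so replicate 3 did not stand out. Within the 6915 genes past the threshold, day 0 replicate 3 did so in 17, against 3 and 6 for replicates 1 and 2. Named by rule were 4 such genes, Ifit3 (4.76 against 5.41 and 5.79), Rsad2 (5.20 against 5.77 and 6.02), Trib3 (5.15 against 5.68 and 5.83) and Myc (5.28 against 5.80 and 5.99). It stood that far above in Ccl11 (5.98 against 4.90 and 5.38), as did replicate 1 in Ccl2 (7.68 against 7.18 and 7.07) and replicate 2 in Myh1 (4.67 against 4.17 and 4.17), while replicate 2 stood below in Ccne1 (4.38 against 5.28 and 5.19).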
